A study of Homo sapiens with 6 samples.

How the data were processed

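RNA was measured in 6 libraries of 786-O cells, 3 with a control shRNA and 3 with an shRNA against METTL3. Per the labels' protocols, total RNA was depleted of ribosomal RNA, fragmented and sequenced from both ends on a DNBSEQ platform. The submitters' processing notes name STAR 2.7.10b, Salmon and the GRCh38 build, without saying which step each tool served. The annotation release and whether reads were counted by strand are not given in the sources used here. Because reads without strand cannot be divided between overlapping genes, named genes whose exons overlap those of others, on either strand, are marked as less certain.

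The authors deposited a table of whole-number counts and a table of FPKM values (fragments scaled to transcript length and library total), each with 61860 Ensembl gene rows and 6 columns. The counts were used as deposited for the tests, and the deposited FPKM values were used for the METTL3 level and for alternatives. The 3 columns named for a control shRNA were taken as the control group. The other 3 columns carry the number of a construct that no label explains, and they were assigned to the METTL3 shRNA group by elimination, since the series holds 2 groups of 3. The level of METTL3 is the check of that assignment. The column letters A, B and C are not tied to the replicate numbers of the labels, and no other columns of values were present.

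Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr, which left 18740, scaled by TMM, and tested with the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values are counts scaled to the TMM-adjusted library total. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom from 16.5 to 62.8), so none was taken as a repeat of another. Total counts ran from 100534896 to 103624456 per library, so that the spread between libraries, more than counting error, limits the precision of all but weakly expressed genes.

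Gene lists were compared with all other tested genes by camera on log2 CPM with a preset correlation of 0.01, and again with a correlation estimated for each list, and fry was run beside it. Adjustment was over the 27 lists. The lists were those of m6A writers, m6A erasers and readers, 2-hydroxyglutarate metabolism, serine and one-carbon metabolism, ATF4 response, methionine cycle and polyamines, HIF targets, glycolysis, interferon-stimulated genes, NF-kB and cytokines, p53 targets, G2 and mitosis, G1/S and DNA replication, mesenchymal genes, epithelial genes, cholesterol biosynthesis, fatty acid synthesis and lipid storage, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, ribosome biogenesis and MYC targets, histones, immediate-early transcripts, chaperones of the endoplasmic reticulum, NRF2 targets, lysosome and autophagy, and nuclear and snoRNA-host noncoding RNAs. In addition, 6 sets of markers of other cell types were read out gene by gene.

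The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Genes were named if they were METTL3, the 12 largest rises or falls past the threshold with an average of at least 2 CPM and no overlap between the groups, leaving out pseudogenes by annotated type and unnamed loci, the up to 4 members of each list with the smallest p, the m6A writers, or one of a few enzymes and erasers chosen in advance. Some genes that met this rule are not reported here. Members named because they were the few exceptions in a list, and members of the gene families in the closing section, were chosen after their values were seen.

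Gene type, position, exon structure and GC content came from GENCODE 29 on GRCh38, in which 58308 of the 61860 identifiers were found. Where a symbol was repeated in the table, which was so for 1292 rows, the identifier served as the name. The procedure was tested on simulated counts drawn from the means and depths of these libraries. Of the 18740 genes, 200 were changed and 22 p53 targets were shifted besides, and 18484 genes passed the filter again. A far larger share, 33.5%, was called in the data, so the rates below need not carry over. The edgeR test found 12% of those changed 1.25-fold, 58% at 1.5-fold, 74% at 2-fold and 86% at 4-fold (100% at 4-fold above 1 CPM), and 6.25% of its calls were unchanged genes.

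Alternatives were DESeq2-type size factors, scaling by library size alone, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a filter of 0.5 FPKM in 3 libraries, limma on log2(FPKM + 1) without that filter, a fit with the column letter as a block, and the fits leaving out each library in turn. Leaving out the mitochondrial transcripts was added after the data were seen.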

Results

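Gene expression was measured by sequencing of ribosomal RNA-depleted total RNA from 786-O cells, an established line of clear cell renal cell carcinoma that lacks functional VHL, the ubiquitin ligase component that marks hypoxia-inducible factors for degradation. The cells stably expressed either a control short hairpin RNA (shRNA) or an shRNA against METTL3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA. Each group held 3 libraries, identified here by the letters A to C of the deposited tables. The total count per library ran from 102420127 to 103624456 in the control group and from 100534896 to 101473388 in the knockdown group. The comparison asks which transcripts differ when METTL3 is reduced, in a study of the roles of m6A in renal cancer with high L-2-hydroxyglutarate. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

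METTL3 was lower in every knockdown library. The gene (ENSG00000165819) lies on the minus strand of chromosome 14, from 21498133 to 21511375 in GRCh38, and its chosen reference transcript has 11 exons. METTL3 received 3874, 4060 and 4141 counts in control libraries A, B and C, and 1064, 956 and 1145 counts in knockdown libraries A, B and C. Its level was 37.6 ± 0.43 CPM (SD, n = 3) in the control group and 10.8 ± 0.87 CPM (SD, n = 3) in the knockdown group. CPM are counts scaled to the TMM-adjusted library total. METTL3 was 71.2% lower (log2 fold change −1.80, SE 0.08, edgeR adjusted p = 1.45e-07). The deposited FPKM values were 24.3 ± 1.21 and 7.18 ± 0.78 (SD, n = 3 each). METTL3 overlaps TOX4 on the opposite strand, and whether reads were counted by strand is not given in the sources used here, so counts of the pair cannot be told apart with certainty.

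**Figure D1:**
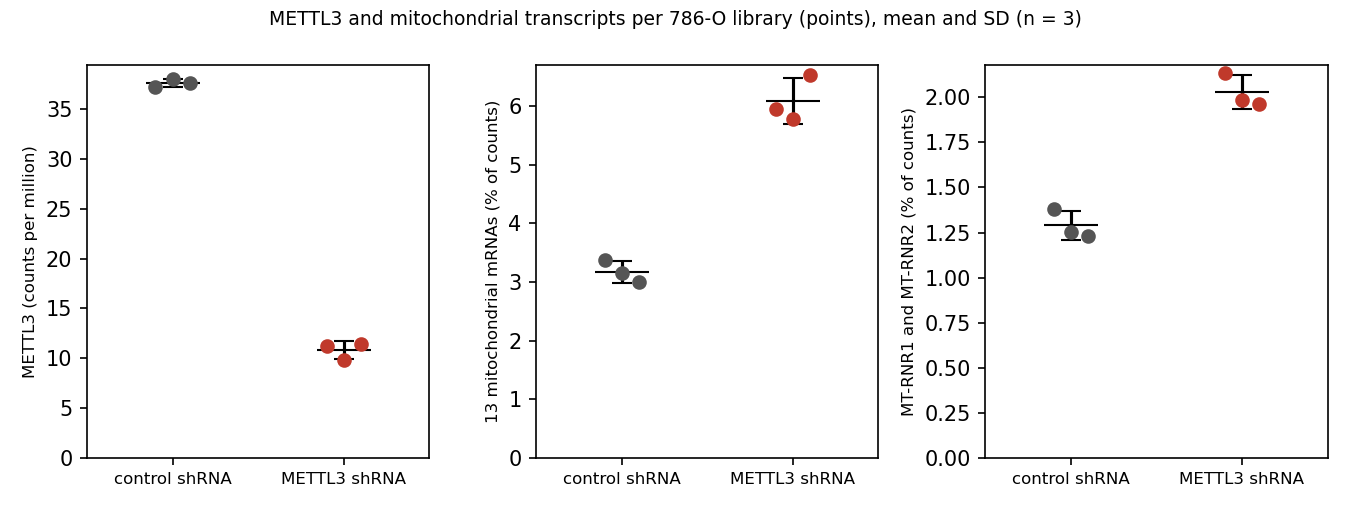
METTL3 in CPM, and the shares of all counts from the 13 mitochondrial mRNAs and from the mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2, in each library. Points are libraries, and horizontal bars with whiskers are the mean and SD of 3 libraries. METTL3 averaged 37.6 CPM in the control group and 10.8 CPM in the knockdown group, and the mitochondrial mRNA share averaged 3.17% and 6.09%.

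All 26 measured genes of G2 and mitosis rose in the METTL3 knockdown libraries, with a median log2 fold change of 0.81, and all 13 mitochondrially encoded mRNAs rose, with a median of 1.05. Of the 35 interferon-stimulated genes measured, 31 fell (median −0.57), and of the 27 genes of ribosome biogenesis and MYC targets, 22 fell (median −0.39). As whole lists against all other genes these 4 did not pass with an estimated correlation (adjusted p = 0.525 for G2 and mitosis and 0.422 for each of the others). The largest single rise was that of SYT13, a synaptotagmin, and the largest single fall was that of CCL5, a chemokine that attracts leukocytes, among the genes that met the rule for naming.

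Of 18740 genes tested, 3099 were higher and 3171 were lower in the knockdown libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which together made up 33.5% of the genes tested. At least 2-fold changes were found for 436 genes that rose and 403 that fell, and the median absolute log2 fold change of the changed genes was 0.46. The knockdown libraries lay entirely above or below the control libraries for 47.4% of the genes, where chance gives 10%. The first principal component held 56.0% of the variance and separated the groups. Scaling by library size alone moved the median log2 fold change of all genes from −0.0030 to −0.11 and the share of higher genes among those changed from 49.4% to 29.6%, so directions of small changes are relative to the scaling. Without knockdown library B, 2053 genes were higher and 1959 lower, and without control library C the number at least 2-fold lower was 257.

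SYT13 (chromosome 11, 45240301 to 45286319) rose from 2.92 ± 0.47 to 15.4 ± 2.53 CPM (SD, n = 3 each), a log2 fold change of 2.40 with an SE of 0.14. PTGS1, which encodes cyclooxygenase 1 (chromosome 9, 122370530 to 122395703), rose from 11.7 ± 3.79 to 54.7 ± 16.9 CPM (2.22, SE 0.24). HILPDA, a lipid droplet protein induced by hypoxia, rose by a log2 fold change of 1.86 (SE 0.15). The next largest rises were those of FZD8, a Wnt receptor (1.75, SE 0.20), AK5, an adenylate kinase (1.71, SE 0.19), LURAP1L (1.62, SE 0.20) and PNMA2 (1.45, SE 0.11), together with the mitotic genes KIF20A (1.60, SE 0.13), SPC24 (1.60, SE 0.18) and CDCA3 (1.62, SE 0.15). CCDC183 (1.75) and MT-ATP8 (1.49) complete the 12 largest rises. SYT13, CCDC183, CDCA3, KIF20A, SPC24 and PNMA2 overlap other genes on the opposite strand, HILPDA, FZD8 and CCDC183 overlap others on the same strand and MT-ATP8 overlaps MT-ATP6, so their counts are less certain.

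CCL5 (chromosome 17, 35871491 to 35880793) fell from 76.5 ± 16.9 to 17.0 ± 2.60 CPM (SD, n = 3 each), a log2 fold change of −2.17 with an SE of 0.15. NPPB, the precursor of B-type natriuretic peptide (chromosome 1, 11857464 to 11858931), fell from 17.7 ± 2.06 to 3.95 ± 1.16 CPM (−2.16, SE 0.16). ADAMTS15, a secreted metalloprotease (chromosome 11, 130448974 to 130476641), had a log2 fold change of −2.03 (SE 0.13). Genes of the interferon response were also among the 12 largest falls, with EPSTI1 at −1.65 (SE 0.20), MX2 at −1.53 (SE 0.18) and RSAD2 at −1.39 (SE 0.10). The others were the spectrin SPTBN5 (−1.53), the epithelial transcription factor GRHL1 (−1.51), the chemokine CXCL16 (−1.45), OR2I1P (−1.45) and UCKL1-AS1 (−1.38). SPTBN5, OR2I1P, CXCL16, RSAD2 and UCKL1-AS1 overlap genes on the opposite strand.

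**Figure D2:**
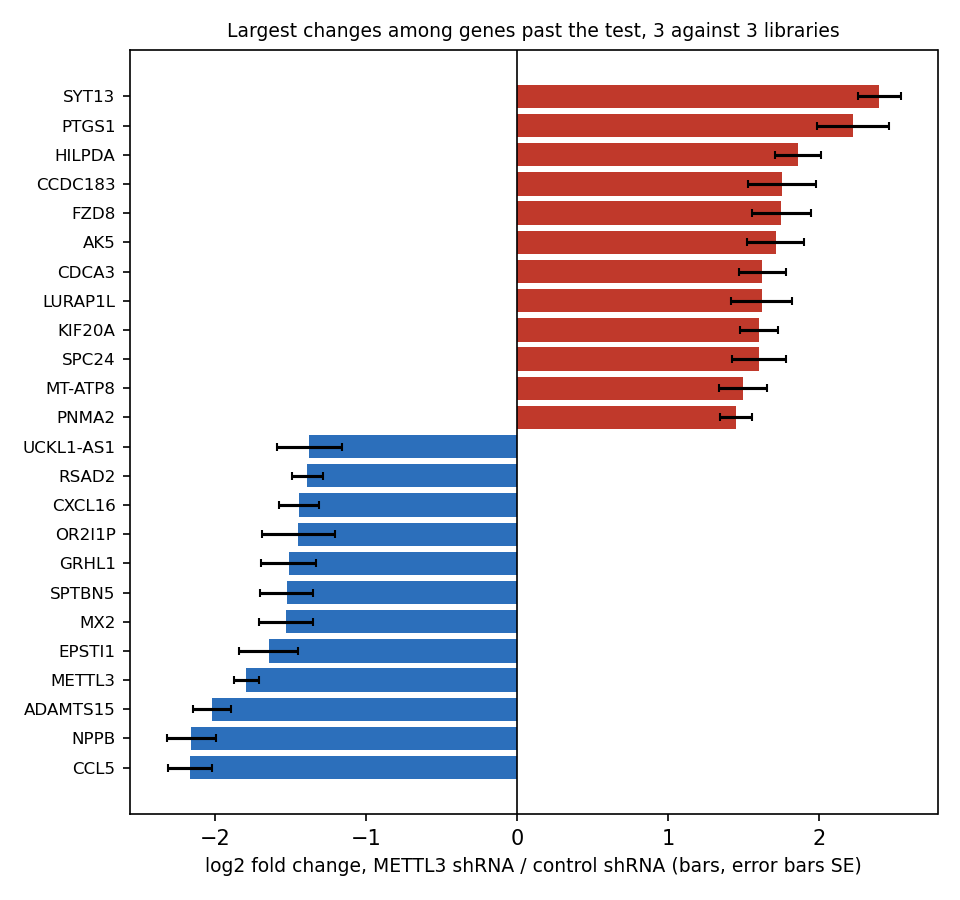
The genes with the largest log2 fold changes, METTL3 shRNA over control shRNA, among genes past the edgeR test that met the rule for naming. Bars are fold changes from 3 against 3 libraries and error bars are SEs. SYT13 had the largest rise (2.40) and CCL5 the largest fall (−2.17), and METTL3 itself stood at −1.80.

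Against all other genes, 9 of 27 gene lists fixed before the data were examined were shifted by camera with a preset correlation of 0.01, 6 of them upward and 3 downward. With a correlation estimated for each list, 0 lists passed (smallest adjusted p = 0.422), and 2 had an unadjusted p under 0.05. The self-contained test fry, which does not compare a list with other genes, passed 7 lists, 6 of these 9 and the epithelial genes. It did not pass G1/S and DNA replication (fry adjusted p = 0.0556), nuclear-encoded oxidative phosphorylation (0.0958) or the cytosolic ribosomal proteins (0.185). The number of lists past camera with the preset correlation was also not particular to the real groups. Of the 10 splits of the libraries into groups of 3, 5 gave at least 9 lists, the real one included. The shifts of whole lists are therefore given below with the number of members that changed one by one. Each call leaves that correlation out, but correlated members tend to pass together, so the counts do not take the place of the test. The estimated correlation was 0.67 for G2 and mitosis, 0.57 for the mitochondrially encoded genes and 0.92 for the cytosolic ribosomal proteins. The 9 lists kept the sign of their median with TMM, DESeq2-type and library size scaling.

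All 26 genes of G2 and mitosis were higher, and 26 were also higher when adjusted over the list alone (adjusted p = 0.525 with an estimated correlation). The kinesin KIF20A, the kinase NEK2 (1.38, SE 0.14), the phosphatase CDC25C (1.23, SE 0.13) and cyclin B2, CCNB2 (0.96, SE 0.10), had the smallest p-values. Of 28 genes of G1/S and DNA replication, 18 rose, 2 fell and 8 did not pass, and 19 rose and 3 fell when adjusted over the list alone (adjusted p = 0.816 with an estimated correlation). Among them E2F1, a transcription factor of S-phase entry, rose by 0.92 (SE 0.10), the replication licensing factor CDT1 by 0.80 (SE 0.12) and the helicase subunit MCM4 by 0.63 (SE 0.10), whereas CCNE1 (−0.64) and UHRF1 (−0.29) were the members that fell. The call of UHRF1 was lost without control library A or C or knockdown library A or C (edgeR adjusted p from 0.0603 to 0.106).

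Transcripts of the mitochondrial genome rose while those of their nuclear-encoded partners fell or did not change past the test. All 13 mitochondrially encoded mRNAs were higher, also when adjusted over the list alone (adjusted p = 0.422 with an estimated correlation). MT-ATP6 rose by 1.34 (SE 0.11), MT-ND2 by 1.24 (SE 0.11), MT-ND4 by 1.19 (SE 0.10) and MT-ND6 by 1.37 (SE 0.13). Their summed share of the counts was 3.17% ± 0.19 in the control group and 6.09% ± 0.39 in the knockdown group (SD, n = 3 each). The mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1, the remainder left after depletion, rose by 0.80 (SE 0.11) and 0.57 (SE 0.11), and their share went from 1.29% ± 0.08 to 2.03% ± 0.09. Of 32 nuclear-encoded subunits of oxidative phosphorylation, 0 rose and 14 fell, and 14 fell when adjusted over the list alone (median −0.16, adjusted p = 0.816 with an estimated correlation). Examples are the complex I subunits NDUFA9 (−0.54, SE 0.09) and NDUFS7 (−0.35, SE 0.08), SDHD of complex II (−0.48, SE 0.08) and UQCRFS1 of complex III (−0.40, SE 0.09). This count was 24 with library size scaling (median −0.28), 6 without knockdown library B (median −0.11) and 9 without control library B.

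Interferon-stimulated genes fell almost throughout. Of 35 measured, 0 rose, 31 fell and 4 did not pass, and 32 fell when adjusted over the list alone (adjusted p = 0.422 with an estimated correlation). The antiviral radical-SAM enzyme RSAD2 fell from 12.9 ± 1.47 to 4.93 ± 0.018 CPM (SD, n = 3 each). IFIT2 fell from 24.4 ± 0.66 to 12.2 ± 0.72 CPM (SD, n = 3 each), the ubiquitin-like modifier ISG15 had a log2 fold change of −0.96 (SE 0.08) and IFI27 one of −0.85 (SE 0.08). The members that did not pass were CMPK2 (−0.51), BST2 (−0.13), MX1 (−0.09) and STAT2 (0.10). Genes of NF-kB signalling and inflammatory cytokines moved both ways, with 2 higher, 5 lower and 16 not past the test of 23, and 2 higher and 6 lower when adjusted over the list alone. Among them the cytokine IL6 fell (−1.35, SE 0.17), as did the chemokine CXCL5 (−0.51, SE 0.08), whereas IL1A rose (1.39, SE 0.34) from 0.103 to 0.271 CPM. The number changed in that list was 3 without knockdown library A, 4 without knockdown library B, control library B or control library C, and 12 without knockdown library C.

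Of 27 genes of ribosome biogenesis and MYC targets, 0 rose and 22 fell, and 23 fell when adjusted over the list alone (adjusted p = 0.422 with an estimated correlation). RRS1 (−0.66, SE 0.08), RRP9 (−0.67, SE 0.08), the rRNA methyltransferase NOP2 (−0.63, SE 0.09) and the nucleolar helicase DDX21 (−0.62, SE 0.09) had the smallest p-values. Of 41 cytosolic ribosomal protein genes, 20 rose, 0 fell and 21 did not pass, and 22 rose when adjusted over the list alone (median 0.31, adjusted p = 0.867 with an estimated correlation). RPS3 rose by 0.76 (SE 0.13), RPS6 by 0.75 (SE 0.13), RPL11 by 0.64 (SE 0.12) and RPS4X by 0.60 (SE 0.12). These genes have many processed pseudogenes that can share their reads, and the number that rose was 12 without control library C, knockdown library A or knockdown library B and 13 without control library B. With library size scaling 13 rose, with a median of 0.20, and without knockdown library A the median was 0.19.

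Long noncoding RNAs of the nucleus and snoRNA hosts rose in 12 of 16 cases and fell in 1, SNHG15 (−0.51), and 13 rose and 1 fell when adjusted over the list alone (median 0.42, adjusted p = 0.422 with an estimated correlation). MALAT1, a nuclear RNA of speckles, went from 131 ± 20.4 to 275 ± 47.4 CPM (SD, n = 3 each), and SNHG12 (0.74, SE 0.11), SNHG5 (0.70, SE 0.11) and SNHG16 (0.68, SE 0.09) rose as well. Of 23 targets of hypoxia-inducible factors, 8 rose, 1 fell and 14 did not pass, with the same counts when adjusted over the list alone (median 0.25, adjusted p = 0.782 with an estimated correlation). Besides HILPDA, the carbonic anhydrase CA12 rose by 1.41 (SE 0.18), the prolyl hydroxylase EGLN3 by 1.03 (SE 0.14) and the glucose transporter SLC2A1 by 0.56 (SE 0.10), and the member that fell was PFKFB4 (−0.40). The call of PFKFB4 was lost without control library C, where it stood at −0.21, and without knockdown library A or B (edgeR adjusted p from 0.0742 to 0.127), and the list median was 0.14 with library size scaling, where 2 members fell. CA9, another target, had at most 2 counts in a library and was not tested.

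**Figure D3:**
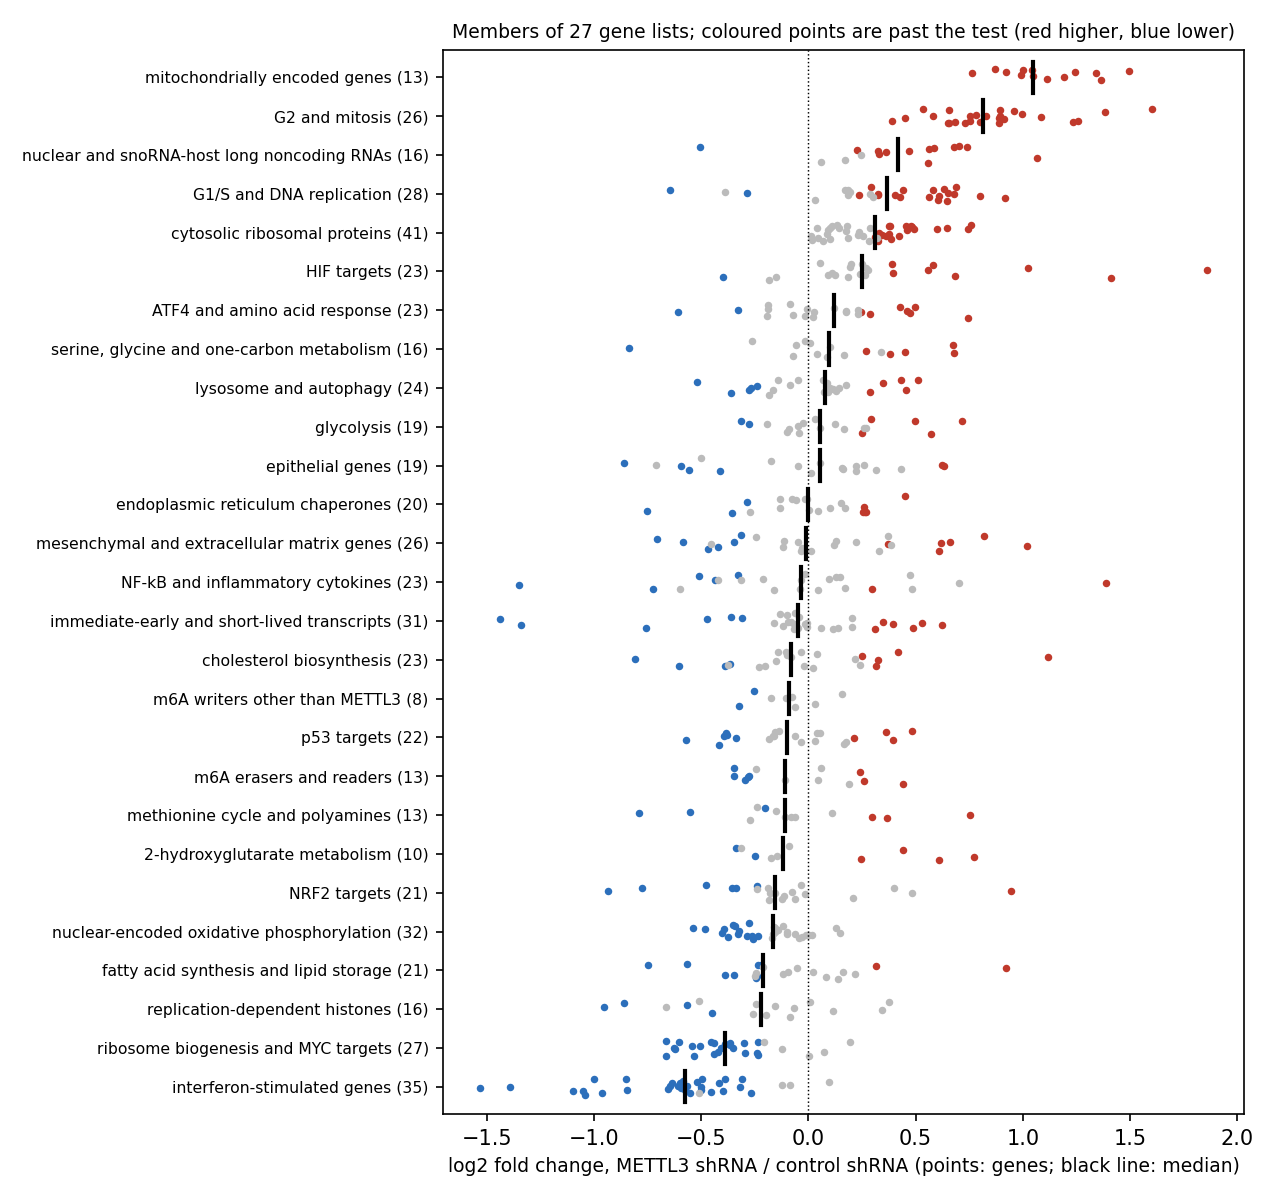
Log2 fold change, METTL3 shRNA over control shRNA, of the measured members of 27 gene lists, with the number measured in parentheses. Points are genes, coloured when past the edgeR test (red higher, blue lower), and black lines are list medians. The medians run from 1.05 for mitochondrially encoded genes to −0.57 for interferon-stimulated genes, and these and the G2 and mitosis list (0.81) hold members almost all on 1 side of 0.

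The other 18 lists did not pass camera (adjusted p from 0.0813 to 0.931). NRF2 targets, at 0.0813, passed in the fits without control library C, knockdown library A or knockdown library B, histones in that without control library A and NF-kB and cytokines in that without knockdown library C. Of the 8 other m6A writer genes, WTAP (−0.32, SE 0.08) and METTL14 (−0.25, SE 0.08) fell, 0 rose and 6 did not pass, with 0 higher and 2 lower when adjusted over the list alone. The values of those not past were −0.18 for VIRMA, 0.16 for RBM15, 0.03 for RBM15B, −0.08 for ZC3H13, −0.11 for CBLL1 and −0.07 for METTL16. Without knockdown library B, 0 writer genes passed, and without knockdown library A or control library B, 1 did. Of 13 erasers and readers of m6A, 3 rose and 5 fell (4 and 6 when adjusted over the list alone), and HNRNPA2B1 (−0.35, SE 0.08), YTHDC2 (−0.35, SE 0.09) and YTHDF2 (−0.28, SE 0.07) fell while IGF2BP2 rose (0.44, SE 0.11). The eraser ALKBH5 rose by 0.24 (SE 0.07), a call lost with library size scaling (edgeR adjusted p = 0.243, with 0.0803 to 0.112 in 3 of the fits without 1 library), and FTO stood at 0.19 (SE 0.08, edgeR adjusted p = 0.0685). The number changed in this list was 5 without control library A or B and 4 without knockdown library B.

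Metabolic lists moved in both directions. In 2-hydroxyglutarate metabolism, 4 of 10 genes rose and 2 fell, with the same counts when adjusted over the list alone, and its median (−0.12) and mean (0.08) differed in sign. With library size scaling 3 rose and 3 fell (median −0.23), and with DESeq2-type scaling 4 rose and 1 fell. The isocitrate dehydrogenases IDH2 and IDH1 rose by 0.77 (SE 0.12) and 0.61 (SE 0.15), the citrate carrier SLC25A1 rose by 0.44 (SE 0.11), and OGDH fell (−0.34, SE 0.08). In serine, glycine and one-carbon metabolism, 5 of 16 rose and 1 fell (6 and 1 when adjusted over the list alone), with AMT at 0.67 (SE 0.14) and TYMS at 0.38 (SE 0.08) higher. PSAT1 stood just short of the threshold (0.34, SE 0.12, edgeR adjusted p = 0.0502), PSPH did not pass (0.10, SE 0.08), and PHGDH, with at most 5 counts in a library, was not tested. In the methionine cycle and polyamine list, 3 of 13 rose and 3 fell (3 and 4 when adjusted over the list alone, 2 and 7 with library size scaling), and MAT2A, the synthase of S-adenosylmethionine, fell from 247 ± 30.01 to 143 ± 6.29 CPM (SD, n = 3 each), AMD1 fell (−0.55, SE 0.09) and CBS rose (0.76, SE 0.17).

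Of 19 glycolysis genes, 5 rose and 2 fell (6 and 2 when adjusted over the list alone), with GAPDH (0.57, SE 0.12) and ENO2 (0.50, SE 0.09) higher, and the number changed was 2 without knockdown library B or control library B and 4 without control library C. Cholesterol biosynthesis had 5 higher and 4 lower of 23 (7 and 7 when adjusted over the list alone), among them INSIG1 at 1.12 (SE 0.12) and PMVK at −0.81 (SE 0.09). Fatty acid synthesis and lipid storage had 2 higher and 8 lower of 21 (3 and 11 when adjusted over the list alone), with the lipid droplet coat protein PLIN2 higher (0.92, SE 0.17) and LPIN1 (−0.75, SE 0.09) and CPT1A (−0.57, SE 0.09) lower, and 5 changed without control library C, knockdown library A or knockdown library B. NRF2 targets had 1 higher and 6 lower of 21, with the same counts when adjusted over the list alone, led by NQO1 (−0.93, SE 0.09), and 4 changed without knockdown library B and 13 with library size scaling. The lysosome and autophagy list had 5 higher and 5 lower of 24, with the same counts when adjusted over the list alone, led by TFEB (−0.52, SE 0.07) and ULK1 (0.46, SE 0.08), and 6 changed without control library B and 5 without knockdown library B.

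The ATF4 and amino acid response list had 7 higher and 2 lower of 23, with the same counts when adjusted over the list alone, with TRIB3 (0.74, SE 0.14) and CEBPB (0.43, SE 0.09) higher and ATF3 lower (−0.61, SE 0.15), and 5 changed without knockdown library A and 4 without knockdown library B. Endoplasmic reticulum chaperones had 5 higher and 3 lower of 20 (5 and 4 when adjusted over the list alone, 1 and 5 with library size scaling), with XBP1 at 0.45 (SE 0.08) and SDF2L1 at −0.75 (SE 0.13), and 4 or 5 changed in the fits without control library A, B or C or knockdown library B. Of 22 p53 targets, 4 rose and 6 fell, with the same counts when adjusted over the list alone, led by CCNG1 (0.48, SE 0.08) and XPC (−0.39, SE 0.07), and 5 changed without control library C, knockdown library A or knockdown library B. Immediate-early and short-lived transcripts had 6 higher and 6 lower of 31, with the same counts when adjusted over the list alone, led by ZFP36 (0.53, SE 0.07) and JUND (0.49, SE 0.08). Replication-dependent histones had 0 higher and 4 lower of 16 (0 and 3 when adjusted over the list alone), with H2BC5 at −0.95 (SE 0.19).

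Mesenchymal and extracellular matrix genes had 6 higher and 6 lower of 26 (6 and 7 when adjusted over the list alone), and their median (−0.01) and mean (0.07) differed in sign. The intermediate filament VIM rose from 1461 ± 234 to 2960 ± 604 CPM (SD, n = 3 each), COL6A1 rose (0.82, SE 0.10) and MMP14 rose (0.61, SE 0.12), whereas TAGLN fell (−0.71, SE 0.12). Epithelial genes had 2 higher and 4 lower of 19, with the same counts when adjusted over the list alone, and the junction protein JUP (−0.86, SE 0.07), the claudin CLDN4 (−0.41, SE 0.07) and the keratins KRT19 (−0.56, SE 0.12) and KRT7 (−0.59, SE 0.13) were those that fell. Their median (0.05) and mean (−0.04) differed in sign, and fry passed this list (adjusted p = 0.0212). With library size scaling the medians of the serine, glycolysis, epithelial and lysosome lists turned from above 0 to below 0, and with DESeq2-type scaling that of the chaperones turned from −0.00125 to 0.00064. Library size scaling also moved the numbers higher and lower to 3 and 4 for glycolysis, 3 and 7 for cholesterol biosynthesis, 1 and 13 for fatty acid synthesis and lipid storage, 1 and 12 for NRF2 targets, 4 and 8 for the lysosome list, 4 and 2 for the serine list, 1 and 8 for NF-kB and cytokines, 1 and 6 for m6A erasers and readers and 0 and 5 for epithelial genes.

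Most markers of other cell types had too few counts to be tested. Endothelial and erythroid markers had at most 12 and 2 counts in any library and were not tested. Of 8 fibroblast markers 3 were tested, and PDGFRB (from 2.15 to 0.929 CPM) and LUM (from 0.347 to 0.117 CPM) fell, with 3 lower when adjusted over the list alone. Of 8 leukocyte markers 3 were tested, and the lysosomal protein CD68 rose (0.95, SE 0.10) while CD14 fell from 0.211 to 0.0788 CPM, with the same counts when adjusted over the list alone. The call of CD14 was lost without control library B or C or knockdown library A or B (edgeR adjusted p from 0.0508 to 0.108) and with DESeq2 (adjusted p = 0.0674). The liver markers ALB (−0.57, SE 0.26) and SERPINA1 (0.08, SE 0.09) did not pass, over all genes or adjusted over the list alone. Of 8 proximal tubule markers tested, 2 rose and 2 fell (2 and 3 when adjusted over the list alone), with the peptidase ANPEP at 0.72 (SE 0.12) and the glucose transporter SLC5A2 at −0.65 (SE 0.13).

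The counts of several genes of the lists and marker sets are less certain because their exons overlap those of other genes on the opposite strand. These are WTAP, RBM15, RBM15B, CBLL1, HNRNPA2B1, ALKBH5, FTO, IDH1, TYMS, CEBPB, MAT2A, SLC2A1, GAPDH, IFIT2, ISG15, CMPK2, MX1, IL6, XPC, CDC25C, VIM, TAGLN, KRT7, LPIN1, SDHD, UQCRFS1, NDUFS7, RPS6, NQO1, MALAT1, SNHG12, SNHG16, SLC5A2 and CD68. On the same strand, MT-ATP6, MT-ND4, AMT, PFKFB4, SLC2A1, IFIT2, NDUFA9, SDHD, RRS1, NOP2, CD68, RPS3, MALAT1 and the RNAs SNHG5, SNHG12, SNHG15 and SNHG16 overlap other annotated genes.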

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

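Only the fit without mitochondrial transcripts was chosen after the data were seen. METTL3 stayed lower past the threshold under each alternative, with a log2 fold change from −1.83 to −1.73 in the fits without 1 library. Scaling by library size gave 1985 genes higher and 4727 lower, and limma on FPKM gave 1588 and 3730 with a pseudocount of 1, 1568 and 3710 with 0.1 and 1027 and 2244 without a filter, so that 29.6%, 29.9%, 29.7% and 31.4% of the genes changed were higher, against 49.4%. At least 2-fold changes numbered 53 up and 35 down with the pseudocount of 1, 143 and 169 with 0.1, 45 and 29 without a filter, and 173 and 124 with a minimum of 1 CPM, which tests fewer genes. The pseudocount shrinks folds of low genes by construction. Leaving out 1 library gave 2053 to 3265 genes higher, 1959 to 3324 lower, 349 to 544 at least 2-fold higher and 257 to 517 at least 2-fold lower. The lowest of the first pair came without knockdown library B and the last lowest without control library C, for which the cause was not tested beyond the fewer libraries. Camera passed 9 to 10 lists in those fits. It passed the same 9 lists and NRF2 targets with limma-voom and filtered FPKM, the 9 and histones without a filter on counts, both more with a minimum of 1 CPM (11), and these, m6A writers and fatty acid synthesis with unfiltered FPKM (13). With all 6 libraries fry passed 7 and camera with an estimated correlation passed 0. Leaving out mitochondrial transcripts gave 8 lists, since 1 list was then empty.

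Named genes that reversed were past no threshold. Of all genes called in the main fit and tested again, 99.5% kept their sign in each fit on FPKM and 100% in each other alternative. With library size scaling SERPINA1 stood at −0.028, PSPH at −0.012, RBM15B at −0.080 and STAT2, at 0.096 in the main fit, at −0.010. With FPKM and a pseudocount of 1 SERPINA1, PSPH and RBM15B stood at −0.020, −0.0028 and −0.074, filtered or not. With a pseudocount of 0.1 these were −0.020, −0.0030 and −0.079. CSF1R, at 0.54 with edgeR, stood at −0.016 with unfiltered FPKM, and leaving out 1 library put RBM15B between −0.023, without control library C, and 0.089. Both scalings shift the median of all genes downward. The alternatives were also tallied for the named genes, the shifted lists and the numbers of changed members in the other lists. Of these values, 18 were newly past the threshold, 96 were no longer past it and 14 reversed in sign. Another 44, all numbers of changed members, moved away from the main count. The other 2794 kept direction and side or, for numbers of members, stayed near the main count.

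With the column letter as a replicate block, 6985 genes were called, against 6270. Deviations from the group means correlated by only −0.02, −0.05 and 0.17 for A, B and C. However, the TMM factors rose from A to C in both groups (1.005, 1.041 and 1.073 in control, 0.940, 0.959 and 0.988 in knockdown). The rho of a library's deviations with mean exon length did so as well (−0.11, 0.006 and 0.083 in control, −0.20, 0.041 and 0.145 in knockdown). Whether libraries of the same letter are paired was therefore left open.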

Other observations

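Apart from the tests of chromosome medians, chromosome 9 windows and exon length, which were written before their results were seen, the tests in this part were chosen only after the results were seen, among them the spread of the exon length relation over libraries. Counts below come from 16 gene families taken by symbol, in 32 Fisher tests adjusted together against all tested genes, of which 16.5% rose and 16.9% fell. All families but the antisense, LINC and snoRNA ones held protein-coding genes alone, of which 16.8% rose and 20.5% fell. The background of all tested genes therefore makes falls in those families stand out more than one of protein-coding genes would. Genes within a family are not independent, so these p-values are descriptive. Some members, among them DDX21, DDX58 and KIF20A, also belong to the gene lists above, so the families partly repeat those results.

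Of 51 RNA helicases of the DDX and DHX families, 31 fell and 1 rose (adjusted p = 3.83e-11 for falls), among them DHX33, DDX51 and DDX21. Of 78 mitochondrial ribosomal proteins, encoded in the nucleus, 33 fell and 2 rose (adjusted p = 9.07e-07), while the mRNAs of the mitochondrial genome rose. Of 48 genes with proteasome (PSM) symbols, 23 fell, PSME2 and PSMB9 among them (adjusted p = 3.49e-06 for falls). The 1 that rose was PSMC3IP, which was taken in by its symbol and is not a proteasome subunit. Of 456 ZNF zinc finger genes, 117 fell and 33 rose (adjusted p = 8.36e-06). Falls were also more frequent than among all tested genes in 8 chaperonin subunits (5 fell) and 11 SR splicing factors (6 fell, adjusted p = 0.0114 each). The same held for 60 heat shock proteins (19 fell, adjusted p = 0.0114) and 20 cytosolic aminoacyl-tRNA synthetases (8 fell, adjusted p = 0.0231). Falls against protein-coding genes alone were not tested. Of 35 kinesins, 15 rose and 2 fell (adjusted p = 0.000761 for rises), led by KIF20A, KIF18B and KIF2C. Without knockdown library B, 17 mitochondrial ribosomal proteins, 14 proteasome genes, 56 zinc finger genes, 2 SR splicing factors, 3 chaperonin subunits and 5 tRNA synthetases fell, and 18 zinc finger genes rose. Without control library B, 15 proteasome genes, 2 SR splicing factors and 5 tRNA synthetases fell, and 20 zinc finger genes rose. Without control library C, 3 chaperonin subunits and 68 zinc finger genes fell, and without knockdown library A, 70 zinc finger genes did. With library size scaling 50 mitochondrial ribosomal proteins and 4 kinesins fell, and 18 zinc finger genes rose. KIF20A, KIF2C, PSME2 and PSMB9 overlap other genes on the opposite strand, and DHX33, PSME2 and PSMB9 on the same strand, so their counts are less certain.

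Of 632 tested RNAs named as antisense to another gene, 128 (20.3%) rose and 42 (6.6%) fell. Of 328 LINC intergenic RNAs, 73 (22.3%) rose and 24 (7.3%) fell. The larger departure from all genes was the rarity of falls (adjusted p = 4.22e-13 and 3.14e-06, against 0.0231 and 0.0145 for rises). Whether low counts limited the falls called was not tested. Counts of antisense RNAs are less certain, as counting by strand is not given. With library size scaling 80 antisense RNAs rose and 59 fell, and 50 LINC RNAs rose and 32 fell. The medians were then 0.03 and 0.08 in place of 0.14 and 0.19. Without knockdown library A or B, 85 and 83 of the antisense RNAs rose and 26 and 20 fell, and 15 and 13 of the LINC RNAs fell. Without control library B, 24 antisense RNAs fell. Of 13951 protein-coding genes, 2338 were higher and 2861 lower (median −0.03), and with library size scaling 1462 were higher and 4267 lower (median −0.14). Initiation factors (adjusted p = 0.0502 for falls), solute carriers, protocadherins, vacuolar ATPase subunits and snoRNAs passed in neither direction.

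The mitochondrially encoded mRNAs rose by a median of 1.05. Scaling alone would not give this, since with library size alone the median was still 0.94 while all genes shifted by −0.11. Less complete removal of ribosomal RNA predicts that MT-RNR1 and MT-RNR2 rise at least as much as the mRNAs, but the log2 ratio of summed mRNA to ribosomal RNA counts was higher by 0.28 in the knockdown group, with a pooled SD of 0.096. What stays open is whether the amount per cell rose. A fall of nuclear-encoded RNA per cell would raise the mitochondrial share by the same log2 amount, 0.94, and without a spike-in this cannot be told apart from a rise of mitochondrial RNA, so an effect of METTL3 loss on mitochondrial transcripts remains a hypothesis.

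The fall of interferon-stimulated genes did not rest on 1 library, since at least 24 of 35 fell in every fit without 1 library, the lowest without control library B. Nor did it rest on scaling, since at least 31 fell under TMM, DESeq2-type and library size scaling. An interferon response of the control line to its own shRNA or virus may also be the source of the difference, and with 0 libraries from cells without an shRNA this cannot be told apart from an effect of METTL3 loss. The same holds for an off-target effect of the hairpin, which was not tested because the knockdown columns carry a single construct number.

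Stable lines can differ in chromosome copies. A gain or loss of a whole chromosome in one line predicts a shift of its genes by at least 0.3, but no chromosome's median lay farther than 0.11 from that of all 13924 protein-coding genes placed on chromosomes 1 to 22 and X. That value, for the 565 genes of chromosome 9, was still larger than in most of 10000 shuffles of chromosomes among genes. This permutation test over all chromosomes gave p = 0.0019, treating genes as independent. Of the 22 windows of neighbouring genes on chromosome 9, 17 lay above the median of all genes. Since the chromosome was picked for its high median, that majority adds no support. A gain of a segment in the knockdown line, or its loss in the control line, may lie behind the higher median. The window farthest from the median of all genes stood at 0.29, between the bounds of 0.2 and 0.3 set for it, so the data leave it open. Windows nearly as far out lay on other chromosomes, at −0.29 on chromosome 19, 0.28 on chromosome 16 and 0.27 on chromosome 1. A single window of this size was thus not particular to chromosome 9. Chromosome 9 held more than one such window, however, with the neighbour of the farthest at 0.25 and its last window at 0.26. Its lowest window stood at −0.13. A gain carried by part of the cells was not tested.

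As m6A is sparse near exon junctions and dense in long exons, transcripts with long exons were predicted to rise when METTL3 is reduced. They did not: over 13924 protein-coding genes the log2 fold change had a Spearman rho of −0.044 with mean exon length (jackknife SE over libraries 0.035), and −0.032 (SE 0.019) after GC content, transcript length and expression were taken out, both more than 2 SEs below the bound of 0.05 set for a rise. These are correlations across genes, which are not independent replicates, and leaving out 1 library gave −0.064 to −0.012 before, with −0.012 without knockdown library A, and −0.040 to −0.013 after, with −0.013 without knockdown library B. Because the raw value was already near 0, whether GC content or transcript length biased it cannot be told apart from no relation. Within groups, single libraries deviated with GC content by a rho of up to 0.28 in control library A and −0.37 in control library B, against 0.06 for the difference between the groups, and with mean exon length by −0.20 in knockdown library A and 0.15 in knockdown library C.

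Over the 10 splits of the 6 libraries into groups of 3, 1 split, the real one, gave the 3099 genes higher, 3171 lower, 436 at least 2-fold higher and 403 at least 2-fold lower, and the highest count in another split was 0 for each. For gene lists past camera with the preset correlation, the real split gave 9 and the highest other 13, and 5 of the 10 splits gave at least 9. The splits are too few for a share under 0.05. For the lists that is not the only limit, since other splits gave as many or more.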
